A study of Mus musculus with 96 samples.

How the data were processed

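Gene-level counts of mouse ventricle RNA were analysed in 96 libraries, each assigned to its group by the sex and treatment given in its labels and to its circadian time by its label. Per the labels' protocols, RNA was extracted with RNeasy kits, poly-A selected libraries were made with Illumina mRNA Prep and sequenced on a NovaSeq. The deposited table holds raw counts per gene for each library, made by the authors without normalization. The submitters' processing notes name HISAT2 (an aligner), Picard and HTSeq (a read counter) and the builds GRCm38 and mm10, and their versions are not given in the sources used here. Poly-A selection leaves most RNAs without a tail uncounted, and counts per gene do not separate isoforms. All 96 columns matched the title of a single library and 0 columns were left unmapped. Genes are given by symbol in the table. Of its 55376 genes, 54486 had a symbol found in the GENCODE M21 annotation of GRCm38, as had 15523 of the 15629 tested genes, and coordinates come from that annotation. A further 26 entries have the form of dates in place of a symbol and held 0.1345% of the counts. They were kept as they stand and are not named here.

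The replicates were compared before they were averaged. For the 48 pairs of libraries of one group and time, the chi-square per gene over genes with at least 20 counts ran from 3.86 to 99.6, so no pair agreed within sampling noise and no library was counted as a duplicate. Library totals were 8944955 to 20596194 counts, so 1 count is worth about 0.1 CPM or less, and a count of 0 allows a level of up to 3 counts. Floors cover counting error only, as reads without molecular identifiers are not independent molecules. Exact (Clopper-Pearson) 95% intervals of shares take genes as independent.

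Tests were run in R 4.3.3 with edgeR 4.0.16. Genes with enough counts in at least the libraries of 1 group were kept (filterByExpr by group, minimum count 10), which left 15629. Libraries were scaled by TMM. A single quasi-likelihood model (glmQLFit, glmQLFTest) was fitted to all 96 libraries, with a mean, a cosine and a sine of circadian time at a period of 24 h for each of the 4 groups. It had 12 coefficients and 84 residual degrees of freedom, a common dispersion of 0.02269 and 6.082 prior degrees of freedom. Because every group holds 2 libraries at each of the 12 times, its mean coefficient is an average over the day. Mean differences (sex in vehicle hearts, sex in tamoxifen hearts, tamoxifen in females, tamoxifen in males and the interaction) were tested on 1 degree of freedom, and rhythms and their differences on the 2 coefficients of the cosine and sine. P-values were adjusted by the Benjamini-Hochberg method over the tested genes, and a gene is called past an adjusted p of 0.05. Sex differences are female minus male, tamoxifen effects tamoxifen minus vehicle, and the interaction is the female-minus-male difference in tamoxifen hearts minus that in vehicle hearts. Values after ± are standard errors for log2 changes and amplitudes and standard deviations for CPM. Amplitude is the distance from the fitted mean to the fitted peak in log2 units, and a difference of rhythms is given as the length of the vector between the fitted cosine and sine terms, so it holds both size and phase and has no sign. The numbers of times given beside a call are those of 12 at which the mean of the libraries lay in the fitted direction. CPM of single libraries are raw, and group means are TMM-scaled unless stated.

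The design, the alternatives to it, 35 gene lists and the rule for named genes were fixed before the data were examined. The lists cover the clock (activating arm, repressors with outputs, other clock-controlled outputs), glucocorticoid targets, cardiac ion channels, calcium handling, sarcomere, cardiac stress markers, fatty acid oxidation, glucose and insulin, nuclear and mitochondrially encoded oxidative phosphorylation, extracellular matrix, integrated stress response, p53 targets, heat shock, interferon response, cell cycle, X escape genes, Y-linked genes, sex steroid signalling, immediate early genes, and markers of cardiomyocytes, atrial, endothelial, fibroblast, mural, macrophage, lymphocyte, neutrophil, erythroid, adipocyte, Schwann, skeletal muscle and mesothelial cells. Some genes stand on more than 1 list, and cardiomyocytes or other ventricular cells also express several of the markers. Lists were tested with camera (limma 3.58.1) on voom values with its preset correlation, with an estimated correlation, and with fry, adjusted over the 33 lists with enough tested members. Adipocyte and skeletal muscle markers, with 1 and 2 tested members, had no set test. With an estimated correlation the calls that held were the X escape and Y-linked lists in both sex comparisons and fibroblast markers in tamoxifen hearts.

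Named genes are every clock list member, in each mean comparison the 8 highest and 8 lowest log2 changes among called genes with at least 5 CPM over the libraries compared, in each group the 8 largest amplitudes among called genes with at least 5 CPM, in each test of rhythms the 6 lowest p-values, and up to 4 members of lowest p from each list. Predicted gene models, the Y-linked list and Xist were left out of these rankings and are given apart. Gm12966 was named after its values were seen, as 1 of 6 genes called. A gene that met more than 1 part of the rule counts under each. Some genes that met the rule are not reported here.

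Tools were tested on simulated counts with the fitted spreads of these libraries and, for each gene, 1 mean level over all of them. The simulation held no other differences between groups, times or libraries and few changed genes, so recovery in the real counts can differ. Of 100 changed genes among 15629 in the sex comparison of vehicle hearts, edgeR recovered 86% at 1.25-fold and 100% at 2-fold, with 98 calls of which 5 were unchanged genes. Of 100 rhythmic genes in vehicle females it recovered 46% at an amplitude of 0.2 and 98% at 0.5, with 80 calls of which 8 were unchanged. DESeq2 1.42.0 recovered 88%, 100%, 50% and 98%, and limma 86%, 100%, 46% and 98%.

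Alternatives fixed beforehand were DESeq2 size factors, library size alone, no filter beyond 1 count in the table (with the trend of spread taken from the filtered genes), limma voom with sample quality weights, DESeq2, a fold of at least 1.5, a linear trend over the 48 h, time as a factor of 12 levels, a 12 h harmonic, the first and the second 24 h alone, each time point left out, only the groups compared, a term for runs of title numbers in tamoxifen libraries, and, for the share of sex-biased genes, no X or Y genes. Chosen after seeing the data were the TEC share as a covariate, thinning of all libraries to the smallest total, a smooth correction of each library for transcript length and GC content (mgcv 1.9.3), and fits without 10 vehicle male libraries with a high TEC share, without 5 tamoxifen libraries with Arntl under 6 CPM, without the library labelled tamoxifen female 559 with Xist under 1 CPM, without these 16 together, and without 13 libraries with Myl7 above 20 CPM. Leaving out libraries that were picked from their own values shows only how far a result depends on them. Title numbers fell in separate runs for vehicle males (2 to 35), vehicle females (403 to 458) and tamoxifen hearts of both sexes (502 to 601), and no source used here calls these runs batches.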

Results

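RNA from the heart ventricles of mice that carry an inducible, cardiomyocyte-specific knockout of Bmal1 (gene symbol Arntl, the activating transcription factor of the circadian clock) was sequenced in 96 libraries. The study asked what part Bmal1 plays in the differences between female and male hearts across the day. Mice had received tamoxifen, the drug that switches on the recombinase, or vehicle, which gave 4 groups of 24 libraries: vehicle females, vehicle males, tamoxifen females and tamoxifen males. Each group was sampled at 12 times from ct 18 to ct 62, every 4 h over 48 h, with 2 libraries per time. The label ct was read as circadian time in hours. Because tamoxifen induces the knockout, the drug and the knockout could not be separated. The labels do not say that the libraries came from separate animals, so the p-values measure the spread between these libraries. Totals ran from 8944955 to 20596194 counts per library. Means were 16385396 ± 2279071 in vehicle females, 12972538 ± 1697841 in vehicle males, 15852469 ± 1772742 in tamoxifen females and 15863681 ± 1973940 in tamoxifen males (SD, n = 24 each).

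The targeted gene was read first. Arntl (ENSMUSG00000055116.8, chromosome 7, 113207465 to 113314126, GENCODE M21 on GRCm38) swung between a peak near subjective dawn and a deep trough in vehicle hearts, and swung far less in tamoxifen hearts. In vehicle females the mean of the libraries went from 47.2 CPM (counts relative to the library total) at ct 26 to 1.46 CPM at ct 34 and back to 48.1 CPM at ct 50. Vehicle males went from 46.2 CPM at ct 26 to 1.55 CPM at ct 34 and 37.9 CPM at ct 50. Tamoxifen females showed 26.2 CPM at ct 26, 12.3 CPM at ct 34 and 27.9 CPM at ct 50, and tamoxifen males 25.5, 8.31 and 31.4 CPM at the same times. Fitted peak-to-trough ranges were 27.3-fold and 17.2-fold in vehicle females and males against 3.33-fold and 3.36-fold in tamoxifen females and males. The change of the Arntl rhythm with tamoxifen passed the test in females (difference vector 1.55 ± 0.21 log2, adjusted p = 1.186e-05) and in males (1.20 ± 0.22, adjusted p = 0.0006305). Whole-gene counts include exons outside a deleted part and cells other than cardiomyocytes, so this count checks the labels only in part.

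**Figure D1:**
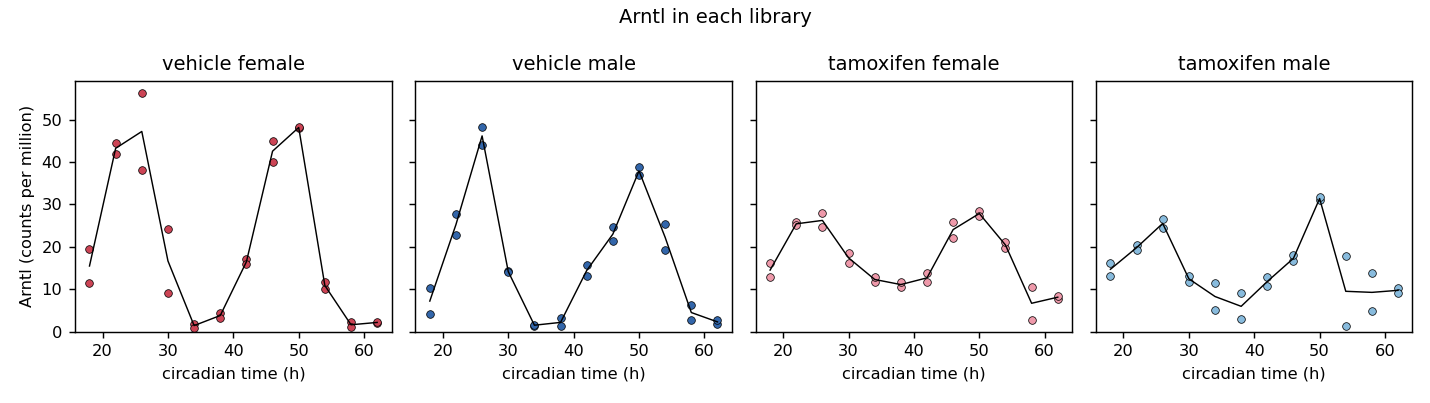
Arntl level in CPM against circadian time in hours, one point per library, in the 4 groups, with lines through the mean at each time. Vehicle groups fell close to 0 at the trough, while most tamoxifen libraries stayed above 6 CPM.

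The arithmetic mean of Arntl fell from 20.45 ± 18.52 to 17.57 ± 7.679 CPM in females and from 16.35 ± 13.95 to 15.11 ± 8.352 CPM in males (SD, n = 24, TMM-scaled). On the log scale the fitted mean rose by 0.44 ± 0.15 in females (adjusted p = 0.0195, higher at 6 of 12 times) and by 0.37 ± 0.15 in males (adjusted p = 0.0287, higher at 5 of 12 times), because the troughs had filled while the peaks were lower. The call for the mean was lost in females without ct 22 (0.41) or ct 34 (0.35). In males it was lost without ct 18 (0.33), ct 22 (0.35), ct 26 (0.35), ct 34 (0.27), ct 50 (0.29) or ct 62 (0.30), with library size alone as the scaling (0.28) and with a correction for transcript length and GC content (0.29).

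Some libraries stood apart from their group. The library labelled Tam_F_ct54_559 held 0.2715 CPM of Xist, the RNA that coats the inactive X, where tamoxifen females averaged 275.6 ± 77.74 and vehicle females 360.0 ± 54.66 CPM. It also held 11.3 CPM of the Y-linked Ddx3y. Arntl lay under 6 CPM in 5 tamoxifen libraries, those labelled Tam_F_ct58_565 (2.845 CPM), Tam_M_ct34_526 (5.169), Tam_M_ct38_531 (2.957), Tam_M_ct54_556 (1.309) and Tam_M_ct58_562 (4.834). At ct 54 vehicle males held 19.2 to 25.3 CPM of Arntl, 7.89 to 11.85 CPM of Per2 and 6.415 to 6.938 CPM of Ciart, where Tam_M_ct54_556 held 1.309, 87.19 and 20.63 CPM. Myl7, the atrial regulatory light chain, exceeded 20 CPM in 13 libraries, of which 7 were vehicle females, 3 vehicle males, 1 tamoxifen female and 2 tamoxifen males. Vehicle males differed from every other group in the share of counts that fell in genes of the annotation's TEC class, transcribed regions that await experimental support. That share averaged 0.1166% (0.08121 to 0.1895%) in vehicle males against 0.09581%, 0.09012% and 0.09175% in vehicle females, tamoxifen females and tamoxifen males. It lay above the highest library of the other groups, 0.1114%, in 10 vehicle male libraries. Counts of called genes and the largest mean changes in comparisons that use vehicle males are therefore also given without these 10 libraries, a choice made after seeing the data.

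**Figure D2:**
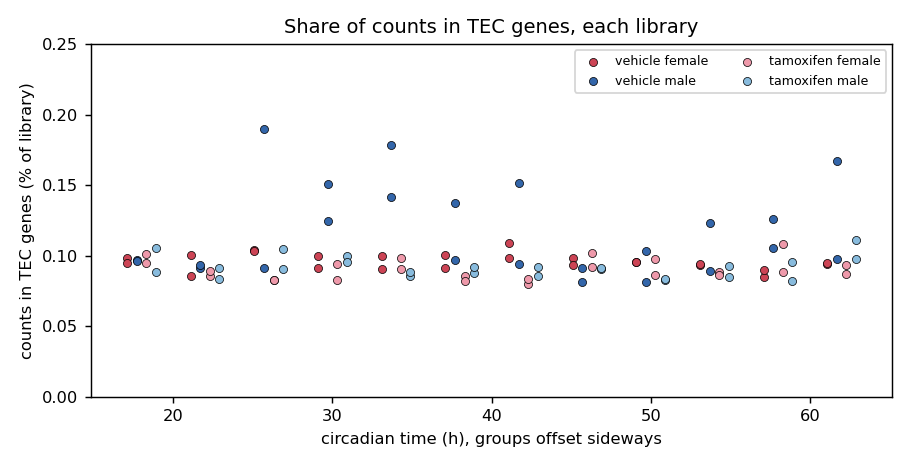
Share of counts in genes of the TEC class, in percent, against circadian time, one point per library, in the 4 groups. In 10 vehicle male libraries the share lay between 0.1228 and 0.1895%, above the highest library of any other group (0.1114%).

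Mean levels of clock genes were compared next. Of 29 tested members of the clock lists, 23 changed in mean level in females, where 27.51% of all tested genes changed, and 21 in males, where 69.97% did. In the activating arm, Npas2 rose by 1.20 ± 0.13 log2 in females and 1.28 ± 0.13 in males, and Clock, the partner of Bmal1, by 0.54 ± 0.06 and 0.59 ± 0.06. Rorb rose by 1.02 ± 0.13 and 1.0 ± 0.13, while Rora fell slightly (−0.28 ± 0.04 and −0.20 ± 0.04). Among the repressors, Cry1 (0.85 ± 0.07 and 0.90 ± 0.07), Cry2 (0.23 and 0.52) and Nfil3 (1.12 ± 0.10 and 1.02 ± 0.11) rose. Several other clock genes were lower, with Ciart at −1.92 ± 0.27 and −1.62 ± 0.24, Nr1d2 at −1.10 ± 0.10 and −0.92 ± 0.10, Per3 at −0.79 ± 0.13 and −0.74 ± 0.13, Dbp at −0.64 ± 0.15 and −0.82 ± 0.15 and Nr1d1 at −0.47 ± 0.10 and −0.61 ± 0.10. Tef, Usp2, Coq10b and Nampt fell in both sexes, Nampt at −1.07 ± 0.09 in females and −0.41 ± 0.09 in males. Klf15 fell in females (−0.33 ± 0.08) and rose in males (0.29 ± 0.08). Mean levels of Per1, Per2 and Bhlhe41 did not pass the test in either sex.

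As a list, the activating arm had 5 members higher and 1 lower of 6 in females (camera adjusted p = 0.000373, and adjusted p = 0.2211 with an estimated correlation) and the same split in males (adjusted p = 0.06428). Clock-controlled outputs had 0 higher and 7 lower of 9 in females (adjusted p = 2.199e-05, and adjusted p = 0.1828 with an estimated correlation) and 1 higher and 5 lower in males, where camera gave no call. Repressors and the outputs listed with them had 3 higher and 7 lower of 14 in females and 3 higher and 6 lower in males. Between the sexes 13 of 29 clock members differed in vehicle hearts (as did 68.32% of all genes). In tamoxifen hearts 1 did (7.684%), Cry1 (0.23 ± 0.07, adjusted p = 0.03396). In vehicle hearts 2 of the activating arm, Clock (0.20) and Rora (0.10), were higher in females, as were 4 repressors including Cry1 and Cry2, while Dbp was lower. Of the outputs 5 were higher, including Klf15 (0.56 ± 0.08) and Nampt (0.41 ± 0.09), and Tspan4 was lower (−0.34 ± 0.07). Rora turned to −0.10 (adjusted p = 0.009094) with the length and GC correction, and lost its call with library size alone (0.06).

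Tamoxifen in females raised Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, from 29.16 ± 18.51 to 113.4 ± 41.77 CPM (4.26-fold, adjusted p = 1.395e-19). It raised Slc41a3, a magnesium transporter gene, from 78.87 to 261.6 CPM (3.92-fold, adjusted p = 3.003e-22) and the methyltransferase gene Inmt by 1.84 ± 0.23 log2. The growth factor gene Ptn (1.63 ± 0.18), the matrix genes Cilp (1.53 ± 0.21) and Ccn5 (1.32 ± 0.14), the potassium channel gene Kcnj14 (1.38 ± 0.39, not called in either 24 h alone) and the vesicular glutamate transporter gene Slc17a7 (1.35 ± 0.13) also rose. The lipid hydrolase gene Ces1d fell from 260.4 ± 55.56 to 46.37 ± 40.15 CPM (log2 change −2.49 ± 0.21, adjusted p = 7.745e-17) and Ptgds, which encodes a prostaglandin D2 synthase, from 305.6 to 81.54 CPM (−1.91 ± 0.17). Ciart, Ano4 (−1.76 ± 0.13), Cntn5 (−1.59 ± 0.15) and the channel subunit gene Cngb3 (−1.53 ± 0.15) fell as well. Myl7 (−3.78 ± 1.32, adjusted p = 0.006136) and the atrial light chain gene Myl4 (−2.15 ± 0.80) passed the test. Without the 13 libraries high in Myl7, however, the Myl7 value was −0.86 and not called. The Myl4 call was also lost without ct 18 (−1.84), ct 34 (−1.70), ct 38 (−2.28) or ct 46 (−2.04), though its value moved less.

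By list, 13 of 26 nuclear genes of oxidative phosphorylation rose in females and none fell, by small amounts (Uqcrfs1 0.20 ± 0.05, Ndufa9 0.19 ± 0.05, Cyc1 0.17 ± 0.04, camera adjusted p = 0.000373, and adjusted p = 0.8951 with an estimated correlation). Fibroblast markers had 7 of 8 higher, led by Dcn (0.37 ± 0.07) and Dpt (0.35 ± 0.09), with camera adjusted p = 0.0168, and adjusted p = 0.7924 with an estimated correlation. Extracellular matrix genes had 11 of 24 higher and 1 lower, with Thbs4 at 0.88 ± 0.15 and Col8a1 at 0.45 ± 0.08, but camera missed the threshold (adjusted p = 0.05319). Of 12 cell cycle genes 8 fell, 9 adjusted over the list alone, with Mki67 at −0.84 ± 0.16 and Top2a at −0.65 ± 0.16 (camera adjusted p = 0.000373, and adjusted p = 0.6711 with an estimated correlation). Macrophage markers had 7 of 12 lower, with Cd163 at −0.48 ± 0.09 and Csf1r at −0.26 ± 0.07 (camera adjusted p = 0.002557, and adjusted p = 0.7834 with an estimated correlation).

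Other lists held members that moved both ways in females. Cardiac ion channels had 6 higher and 12 lower of 34 (8 and 14 adjusted over the list alone). The pacemaker channel gene Hcn2 (1.17 ± 0.10) and Kcne1 (0.96 ± 0.13), a subunit of the slow delayed rectifier, rose, and Kcnip2 (−0.71 ± 0.06) and Kcnv2 (−0.86 ± 0.10) fell. Sarcomere genes had 6 higher and 4 lower of 20, with Mybpc3 at 0.32 ± 0.05 against Tcap at −0.67 ± 0.10 and the slow myosin gene Myh7 at −1.23 ± 0.21. Genes of glucose and insulin metabolism had 11 higher and 5 lower of 29 (Irs1 0.49 ± 0.08, Hk2 −0.27 ± 0.05). Fatty acid oxidation had 6 higher and 2 lower of 32, and calcium handling 4 higher and 2 lower of 17. The integrated stress response had 5 higher and 2 lower of 15 with Mthfd2 at 0.90 ± 0.13, and heat shock 4 higher of 14 with Hsph1 at 0.42 ± 0.09. Glucocorticoid targets had 2 higher, Cdkn1a and Ddit4 (1.18 ± 0.13), and 3 lower, among them the metallothionein genes Mt1 (−0.59 ± 0.08) and Mt2 (−0.98 ± 0.17). Of 13 targets of p53, 3 rose, Cdkn1a among them, and 2 fell. Cardiac stress markers had 4 higher and 1 lower of 13, and no member of the interferon list changed.

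In total 4299 of 15629 tested genes changed in mean level with tamoxifen in females, 2381 higher and 1918 lower, with a median change of 0.2298 log2 among those called. Of these, 477 changed by at least 1.5-fold. With library size alone as the scaling the split turned to 1794 higher and 2395 lower of 4189, so the share of higher genes depended on the scaling. Collection runs, as far as title numbers show them, were separate for vehicle and tamoxifen hearts, so treatment and any batch that follows those numbers could not be told apart.

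**Figure D3:**
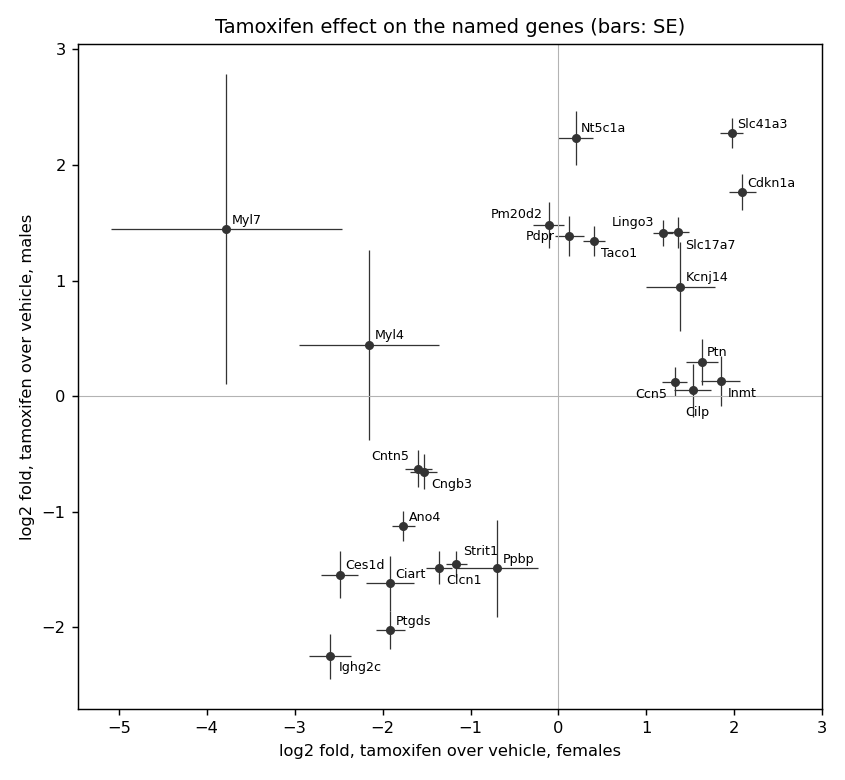
Log2 fold change with tamoxifen in females (horizontal axis) and males (vertical axis), tamoxifen minus vehicle, for genes named for the tamoxifen effect in either sex, with bars of 1 SE. Slc41a3 and Cdkn1a lie high in both sexes and Ces1d, Ptgds and Ciart low in both.

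In males tamoxifen raised Slc41a3 from 52.28 to 224.2 CPM (4.84-fold, adjusted p = 1.633e-25) and Cdkn1a from 24.48 to 86.43 CPM (3.40-fold, adjusted p = 2.502e-16). Slc17a7 (1.42 ± 0.13) and Lingo3 (1.41 ± 0.11) rose too. Ptgds fell from 378.1 to 92.68 CPM (−2.03 ± 0.16) and Ces1d from 206.9 to 70.91 CPM (−1.54 ± 0.20), and Ciart fell. Without the 10 vehicle male libraries high in TEC counts these values were 2.0 for Slc41a3, 1.73 for Cdkn1a, 1.03 for Slc17a7, 1.08 for Lingo3, −2.17 for Ptgds, −1.67 for Ces1d and −1.58 for Ciart. Nt5c1a, a cytosolic nucleotidase gene, rose from 3.667 to 13.64 CPM (2.24 ± 0.24), with 1.66 without the 10 libraries. Pm20d2 (1.48 ± 0.20, then 0.94), the pyruvate dehydrogenase phosphatase subunit gene Pdpr (1.39 ± 0.17, then 0.97) and Taco1 (1.34 ± 0.13, then 0.86) followed. The immunoglobulin gene Ighg2c fell (−2.25 ± 0.19, then −2.49), as did the chloride channel gene Clcn1 (−1.48 ± 0.14, then −1.09) and Strit1, which encodes a micropeptide that activates the calcium pump SERCA (−1.45 ± 0.11, then −1.37). Ppbp, a platelet chemokine gene, passed the test at −1.49 ± 0.42, but its call was lost without the 10 libraries (−0.37), without ct 30 (−0.82) and without ct 38 (−0.84).

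Ion channel genes rose in males more often than they fell, 21 against 7 of 34, with Hcn2 at 1.30 ± 0.11, Kcnd2 at 1.05 ± 0.10 and Kcnj12 at 1.12 ± 0.11 (camera adjusted p = 0.02013, adjusted p = 0.9183 with an estimated correlation, and adjusted p = 0.05141 without the 10 libraries). Calcium handling genes had 11 higher and 2 lower of 17, with Srl at 0.84 ± 0.09, Casq2 at 0.74 ± 0.08 and the release channel gene Ryr2 at 0.69 ± 0.08, and gave the same 3 adjusted p-values. Glucose and insulin genes had 21 higher and 5 lower of 29, with Irs1 at 0.85 ± 0.08 and Akt2 at 0.49 ± 0.05 (camera adjusted p = 0.01051, adjusted p = 0.9183 with an estimated correlation, and adjusted p = 0.5705 without the 10 libraries). Endothelial markers were lower for 10 of 10, including Cldn5 (−0.67 ± 0.10) and Egfl7 (−0.51 ± 0.08), with camera adjusted p = 0.01051, adjusted p = 0.9183 with an estimated correlation, and adjusted p = 0.2958 without the 10 libraries. Without these libraries the oxidative phosphorylation list was called lower (adjusted p = 0.0343) and macrophage markers lower (adjusted p = 0.01818), neither of which was called with them, and an estimated correlation with all libraries gave adjusted p = 0.932 and adjusted p = 0.9183.

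Further lists in males moved without a call from camera with its preset correlation, while fry called 19 lists in all. Fatty acid oxidation had 15 higher and 5 lower of 32 (Acsl1 0.76 ± 0.09, Etfb −0.89 ± 0.11), heat shock 10 higher and 2 lower of 14, sarcomere 9 higher and 7 lower of 20 (Mybpc3 0.48 ± 0.05, Tcap −0.93 ± 0.10), and oxidative phosphorylation 5 higher and 8 lower of 26 (Ndufs1 0.56 ± 0.08, Cox8b −0.43 ± 0.06). Interferon response genes had 10 of 15 lower (Bst2 −0.47 ± 0.08, adjusted p of the list 0.06428) and cell cycle genes 10 lower and 1 higher of 12 (Ccna2 −0.89 ± 0.15). Glucocorticoid targets had 4 higher and 3 lower, with Ddit4 at 1.17 ± 0.13 and Mt2 at −1.11 ± 0.17. Single markers of other cells were lower in males: neutrophil markers 3 of 3 (S100a8 −2.01 ± 0.31), Schwann cell markers 5 of 5, macrophage markers 8 of 12 (Cx3cr1 −0.80 ± 0.13), and lymphocyte markers 4 of 5 with 1 higher.

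Tamoxifen changed 10936 genes in males, 5031 higher and 5905 lower, with a median change of 0.3271 log2 among those called. Without the 10 libraries the count was 6661, 3620 higher and 3041 lower, of which 5959 were in the first set. Library size alone gave 3825 higher and 7575 lower of 11400. Effects in the sexes, estimated from separate libraries, overlapped: 1432 genes rose in both sexes, where 766.4 would be expected if the calls were independent, and 1054 fell in both, where 724.7 would be. Across the 15629 genes the effects had the same sign for 61.84%, with Pearson r = 0.2416 and Spearman rho = 0.3485, and genes are not independent replicates.

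**Figure D4:**
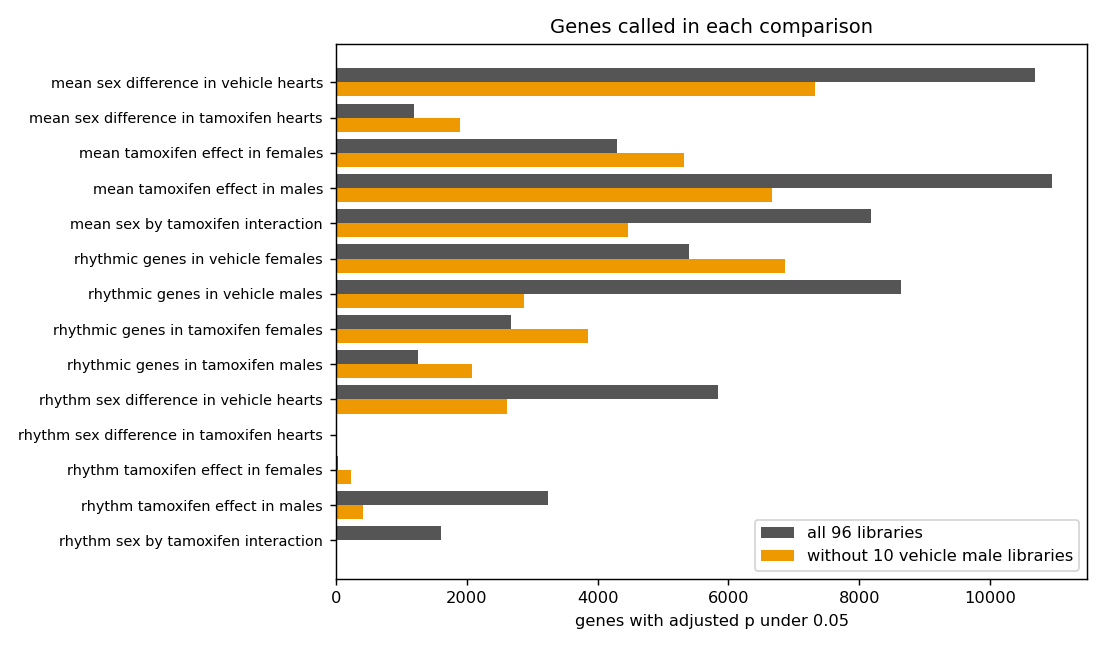
Number of genes past an adjusted p of 0.05 in each comparison of mean levels and of rhythms, with all 96 libraries and without the 10 vehicle male libraries high in TEC counts. The count for the tamoxifen effect on mean levels in males went from 10936 to 6661.

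Female and male vehicle hearts differed in Y-linked genes and genes that escape X inactivation. Ddx3y, Eif2s3y, Kdm5d and Uty had no count in any vehicle female library and means of 158.3, 117.5, 28.66 and 32.79 CPM in vehicle males. A count of 0 allows up to 0.1825 CPM (3 counts) in the median vehicle female library. Escape genes were higher in females for 7 of 7, with Kdm6a at 1.14 ± 0.05, Kdm5c at 1.06 ± 0.06 and Ddx3x at 0.70 ± 0.04 (camera adjusted p = 1.034e-08, and adjusted p = 0.0006951 with an estimated correlation). The Y-linked list had 4 of 4 lower (adjusted p = 4.025e-17, and adjusted p = 0.0001411 with an estimated correlation).

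Outside the sex chromosomes, the complement gene C7 was 6.03-fold lower in vehicle females (4.318 ± 1.174 against 27.39 ± 11.81 CPM, adjusted p = 4.977e-33, lower at 12 of 12 times). The aminopeptidase gene Lvrn (−2.23 ± 0.13), the acute phase gene Serpina3n (−1.83 ± 0.16), Ccn5 (−1.74 ± 0.14), the proenkephalin gene Penk (−1.62 ± 0.11), Ano5 (−1.57 ± 0.18) and Inmt (−1.49 ± 0.23) were also lower in females. Higher in females were Nt5c1a (12.47 against 3.667 CPM, 2.06 ± 0.24), Pm20d2 (1.65 ± 0.19), the amino acid transporter gene Slc38a1 (1.60 ± 0.11), the collagen gene Col14a1 (28.75 against 10.07 CPM, 1.51 ± 0.12) and Kcne1 (1.48 ± 0.15). Without the 10 vehicle male libraries these values were −2.49 for C7, −2.0 for Lvrn, −1.93 for Serpina3n, −1.53 for Ccn5, −1.5 for Penk, −1.60 for Ano5, −1.22 for Inmt, 1.48 for Nt5c1a, 1.11 for Pm20d2, 1.55 for Slc38a1, 1.44 for Col14a1 and 1.32 for Kcne1. Myl7 (3.38 ± 1.23), Myl4 (1.76 ± 0.75) and Dkk3 (1.59 ± 0.55), all on the list of atrial markers, were called higher, Myl7 and Myl4 in step with the libraries high in Myl7. Without those 13 libraries Myl7 was at 0.46 and Myl4 at 0.32, neither called, and without ct 54 Dkk3 was at 1.0 and not called. Myl4 was not called without the 10 vehicle males either (2.40), nor without ct 18 (1.32) and 4 other times. Ppbp (−1.55 ± 0.42) lost its call without the 10 libraries (−0.44) and without ct 38 (−0.74).

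Genes for cardiac ion channels were higher in vehicle females for 24 of 34 and lower for 2, with Kcnj12 at 1.10 ± 0.11 and Kcnj2 at 0.57 ± 0.07, both inward rectifiers (camera adjusted p = 1.924e-05, adjusted p = 0.4205 with an estimated correlation, and adjusted p = 3.351e-05 without the 10 libraries). Calcium handling genes were higher for 13 and lower for 2 of 17, or 3 adjusted over the list alone, with Ryr2 at 0.63 ± 0.08 and the SERCA gene Atp2a2 at 0.61 ± 0.08 (camera adjusted p = 0.01097, adjusted p = 0.6998 with an estimated correlation, and adjusted p = 0.1075 without the 10 libraries). Nuclear genes of oxidative phosphorylation were lower for 17 and higher for 2 of 26, with Cox5b at −0.48 ± 0.05 (camera adjusted p = 0.005917, adjusted p = 0.8946 with an estimated correlation, and adjusted p = 6.236e-11 without the 10 libraries). Endothelial markers were lower for 10 of 10, with Egfl7 at −0.67 ± 0.08 (camera adjusted p = 0.002083, adjusted p = 0.8154 with an estimated correlation, and adjusted p = 0.1977 without the 10 libraries). Without these libraries fatty acid oxidation (adjusted p = 4.842e-06), mitochondrially encoded genes (adjusted p = 0.007582) and cardiac stress markers (adjusted p = 0.03303) were also called lower, where an estimated correlation with all libraries gave adjusted p = 0.9863, adjusted p = 0.8236 and adjusted p = 0.8236.

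The other lists in vehicle hearts were not called by camera with its preset correlation, while fry called 20 lists in all. Glucose and insulin genes had 15 higher and 6 lower of 29 (Irs2 1.04 ± 0.12, Pgam2 −0.59), fatty acid oxidation 6 higher and 9 lower of 32 (Acsl1 0.58, Etfb −0.98). Mitochondrially encoded genes had 1 higher and 8 lower of 13, where the calls of mt-Nd4 (−0.02) and mt-Nd1 (−0.03) were lost with a correction for transcript length and GC content. Sarcomere genes split 8 and 8 of 20, with Ttn at 0.51 ± 0.07 and Tnni3 at −0.41, and their median of 0.06 had the opposite sign to the test. Stress markers had 1 higher and 8 lower of 13, the extracellular matrix 4 and 6 of 24, glucocorticoid targets 3 and 3 of 14 and the integrated stress response 2 and 8 of 15. Next came p53 targets with 5 and 3 of 13, heat shock 5 and 3 of 14, interferon response 1 and 5 of 15, cell cycle 1 and 11 of 12, immediate early genes 2 and 8 of 16, and sex steroid signalling 1 and 1 of 7. Markers of other cells also differed. In females neutrophil markers were lower for 3 of 3 (S100a8 −1.92 ± 0.30), erythroid for 6 of 6, Schwann cell for 4 of 5, lymphocyte for 4 of 5 with 1 higher, macrophage for 8 of 12 with 3 higher, mural for 4 of 8 with 1 higher, and skeletal muscle for both. Mesothelial markers were higher for 5 of 6 and lower for 1. Cardiomyocyte markers had 4 higher and 3 lower of 8, atrial markers 3 higher of 5, fibroblast markers 2 higher and 1 lower of 8, and the adipocyte marker Cfd was higher (2.52 ± 0.78).

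Altogether 10678 genes differed in mean level between vehicle females and males, 4966 higher and 5712 lower in females, with a median difference of 0.3156 log2 among those called and 1378 differing by at least 1.5-fold. Without the 10 libraries 7323 genes were called, 3748 higher and 3575 lower, of which 6108 were in the first set. Vehicle females and vehicle males carried separate runs of title numbers, so sex and run could not be told apart in vehicle hearts.

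In tamoxifen hearts, whose title numbers were interleaved between the sexes, though unevenly, the sex difference took in fewer genes. C7 was again lower in females (4.012 ± 1.285 against 24.11 ± 7.49 CPM, 5.98-fold, adjusted p = 1.796e-32, lower at 12 of 12 times), as were Hsd11b1, whose product regenerates active glucocorticoid (−1.48 ± 0.09), Penk (−1.44 ± 0.12), Ifi205 (−1.25 ± 0.13), Acsm5 (−1.23 ± 0.12), the mitochondrial tRNA gene mt-Tt (−1.01 ± 0.10) and Cpxm2 (−1.0 ± 0.14). Ptn (1.66 ± 0.18, adjusted p = 1.825e-11), Col14a1 (1.43 ± 0.12), Cilp (1.42 ± 0.21), Kcne1 (1.42 ± 0.14), Comp (1.36 ± 0.28), Mfap4 (1.23 ± 0.17), Fibin (1.10 ± 0.12) and Sema3d (0.96 ± 0.13) were higher in females. Of these, Col14a1, Cilp and Comp encode matrix proteins, and Comp was not called in the second 24 h alone (1.08, adjusted p = 0.1281). The heat shock gene Hspa1b was called lower (−1.09 ± 0.34, adjusted p = 0.03003, lower at 6 of 12 times), a call that was lost without ct 18 (−0.68), ct 46 (−1.06), ct 50 (−0.98), ct 54 (−0.38) or ct 62 (−1.08), and with limma (−0.09).

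Connective tissue genes stood out in tamoxifen females. Fibroblast markers were higher for 7 of 8, with Lum at 0.78 ± 0.08, Pdgfra at 0.43 ± 0.06 and Tcf21 at 0.40 ± 0.07 (camera adjusted p = 8.096e-14, and adjusted p = 0.004712 with an estimated correlation). Extracellular matrix genes were higher for 10 and lower for 1 of 24, 11 and 1 adjusted over the list alone, with Bgn at 0.42 ± 0.06 and Thbs4 at 0.88 ± 0.15 (camera adjusted p = 1.777e-07, and adjusted p = 0.31 with an estimated correlation). Interferon response genes were higher for 7 of 15, 9 adjusted over the list alone, with Oasl2 at 0.33 ± 0.08 (camera adjusted p = 7.481e-08, and adjusted p = 0.31 with an estimated correlation). Escape genes were higher for 7 of 7 (Kdm6a 0.91 ± 0.05, adjusted p = 1.415e-41, and adjusted p = 4.992e-14 with an estimated correlation) and Y-linked genes lower for 4 of 4 (adjusted p = 1.262e-94, and adjusted p = 1.053e-17 with an estimated correlation).

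Lists called lower in tamoxifen females held few single genes past the threshold. Fatty acid oxidation had 2 of 32 lower (Decr1 −0.17, Slc25a20 −0.24), with camera adjusted p = 9.429e-05, and adjusted p = 0.6997 with an estimated correlation. Mitochondrially encoded genes had 2 of 13 lower, 5 adjusted over the list alone, with mt-Atp6 at −0.71 ± 0.16 (adjusted p = 0.003326, and adjusted p = 0.4775 with an estimated correlation). Cell cycle genes had 1 of 12 lower, Mki67 (−0.56 ± 0.16), and 5 adjusted over the list alone (adjusted p = 9.429e-05, and adjusted p = 0.3802 with an estimated correlation). Endothelial markers had 1 of 10 lower, Cdh5 (−0.24 ± 0.07), and 2 adjusted over the list alone (adjusted p = 0.01463, and adjusted p = 0.6997 with an estimated correlation).

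The sex difference in tamoxifen hearts covered 1201 genes, 638 higher and 563 lower in females, at a median of 0.288 log2, and 3199 genes had an unadjusted p under the threshold. With library size alone the split was 752 higher and 377 lower of 1129, or 66.6% against 53.1% higher. A fit on the tamoxifen libraries alone called more genes than the main fit, and with a term for the 2 runs of title numbers it gave 2408. Limma gave 2797. Leaving out the 10 vehicle males, which changes only the estimate of spread here, gave 1899, including all 1201.

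Genes with a sex difference in vehicle hearts were then followed into tamoxifen hearts. Of the 10678, 700 were also called with the same sign in tamoxifen hearts, 6.556% (95% interval over genes 6.093 to 7.042%). Higher in females in both were 306 genes, with 202.7 expected if the calls were independent, and lower in both 394, with 205.8 expected. Seen from the tamoxifen side, 700 of 1201 genes, or 58.28%, had also been called in vehicle hearts with the same sign, among them C7, Penk, Col14a1 and Kcne1. Over the genes called in vehicle hearts the slope of the tamoxifen difference on the vehicle difference was 0.729, and 0.1555 without genes on X and Y. Over those called in tamoxifen hearts the slope of the vehicle difference on the tamoxifen difference was 0.7754, and 0.6913 without X and Y, with the same sign for 78.43% and 77.99%. Each set was chosen by its own call, which affects its slope. Without the 10 vehicle male libraries the share was 13.59%, with the TEC share as a covariate 13.44%, and without 16 libraries in doubt 10.42%, so its size depended on these libraries.

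The interaction between sex and tamoxifen tested these differences directly. It takes in the sex difference of vehicle hearts, so it could not be told apart from the run of title numbers that vehicle males alone carried. The largest rises of the female-minus-male difference reported here were in Inmt (1.71), Cilp (1.48), Ptn (1.33), Thbs4 (1.21) and Ccn5 (1.20), which were at 1.45, 1.46, 1.15, 1.29 and 0.99 without the 10 libraries. In the second 24 h alone Inmt (1.05, adjusted p = 0.0632), Cilp (0.96, adjusted p = 0.0961) and Ptn (0.81, adjusted p = 0.1107) were not called. Comp (1.13) lost its call without the 10 libraries (0.68), in the second 24 h alone (0.21), and without ct 26 (0.87) or ct 38 (0.95). The largest falls were in Myl7 (−5.22), Nt5c1a (−2.04), Pm20d2 (−1.59), Pdpr (−1.26), the adenylyl cyclase gene Adcy9 (−1.26), Srp54a (−1.21) and Ppara, which encodes a nuclear receptor of fatty acid metabolism (−1.16). Without the 10 libraries Nt5c1a was at −1.47, Pm20d2 at −1.05, Pdpr at −0.84, Adcy9 at −1.08, Srp54a at −0.78 and Ppara at −1.04. For all of these genes vehicle males alone were low, and the means of the other groups lay close together. Pdpr averaged 49.34 CPM in vehicle males and 101.2, 109.4 and 111.4 CPM in vehicle females, tamoxifen females and tamoxifen males. Their interaction, their female excess in vehicle hearts and their rise with tamoxifen in males thus share the level of a single group. Myl7 was at −0.21 and not called without the 13 libraries high in it, and also lost its call without ct 34 (−1.76) or ct 50 (−0.60). The mitochondrial gene mt-Nd4l (−1.33) lost its call without the 10 libraries (−0.64), without ct 38 (−0.97) or in the second 24 h alone (−0.89).

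Ion channel genes gave the interaction's clearest list, 0 higher and 22 lower of 34, or 24 adjusted over the list alone, with Kcnj12 at −1.03 ± 0.15 (camera adjusted p = 9.846e-05, adjusted p = 0.8896 with an estimated correlation, and adjusted p = 6.896e-05 without the 10 libraries). Calcium handling had 1 higher and 12 lower of 17 (Ryr2 −0.56, adjusted p = 0.01492), glucose and insulin 2 higher and 14 lower of 29 (Gys1 −0.63, adjusted p = 0.02933), the extracellular matrix 11 of 24 higher (Dcn 0.46, adjusted p = 0.04362). Higher were also the interferon response for 9 of 15, or 12 adjusted over the list alone (Bst2 0.57, adjusted p = 0.01421), endothelial markers for 7 of 10, or 8 adjusted over the list alone (Egfl7 0.54, adjusted p = 0.03477), and fibroblast markers for 7 of 8 (Dpt 0.63, adjusted p = 0.01873). Each of these 6 had adjusted p = 0.8896 with an estimated correlation. Oxidative phosphorylation had 14 higher and 2 lower of 26, or 15 and 2 adjusted over the list alone, with Cox5b at 0.46 ± 0.07 (adjusted p = 0.02063, adjusted p = 0.9371 with an estimated correlation, and adjusted p = 2.548e-10 without the 10 libraries). Of the others, fibroblast markers kept their call without the 10 libraries (adjusted p = 0.006351), while calcium handling, glucose and insulin, matrix, interferon and endothelial lists did not. Among clock genes Klf15 (−0.62), Nampt (−0.65), Wee1 (−0.57), Cry2 (−0.29) and Tspan4 (0.28) had an interaction. In all 8181 genes were called, 4216 higher and 3965 lower, and 4463 without the 10 libraries, of which 3747 were in the first set.

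Rhythms with a 24 h period were fitted in each group. Of 29 tested clock genes, 29, 27, 25 and 20 were rhythmic in vehicle females, vehicle males, tamoxifen females and tamoxifen males. The amplitude of Dbp, measured from the fitted mean to the peak, was 2.34, 2.07, 1.96 and 1.74 log2 in that order, of Per2 1.95, 2.03, 1.72 and 1.0, of Per3 1.5, 1.48, 1.69 and 1.27, and of Ciart 1.96, 1.93, 2.64 and 1.77. In the activating arm Npas2 was at 1.32, 1.17, 0.49 and 0.39 (not called in tamoxifen males, adjusted p = 0.0736) and Clock at 0.60, 0.53, 0.36 and 0.20 (adjusted p = 0.0859 in tamoxifen males). The change of rhythm with tamoxifen passed the test for 3 of 6 members of the arm in each sex, and for Clock in males but not in females (adjusted p = 0.2797). Repressors were rhythmic for 14, 14, 14 and 12 of 14 and outputs for 9, 9, 8 and 6 of 9, and Tspan4 kept amplitudes of 0.77, 0.91, 0.87 and 0.86. Other large rhythms were those of Hspa1b (1.87 ± 0.37) and Hspa1a (1.80 ± 0.34) in vehicle females, Spon2 in vehicle females, tamoxifen females and tamoxifen males (1.72, 1.81 and 1.72), Nrgn (1.76 ± 0.39) in vehicle males and Nr1d2 (1.16 ± 0.10) in tamoxifen males.

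Atrial and fat marker genes had the largest fitted amplitudes of all, carried by a few libraries. Myl7 had 4.91 ± 1.56 in vehicle males, 5.32 ± 1.69 in tamoxifen females and 4.20 ± 1.06 in tamoxifen males, and Myl4 2.93 ± 0.85, 3.61 ± 0.94 and 3.56 ± 0.83. Dkk3 in vehicle males (2.03 ± 0.62) and Cfd (3.37 ± 0.73), Car3 (2.99 ± 0.64) and Sbk3 (1.73 ± 0.47) in tamoxifen females were of this kind. Without the library labelled Tam_F_ct54_559 alone, Cfd was at 0.46, Car3 at 0.30 and Sbk3 at 0.64. None of these rhythms was then called (adjusted p = 0.8823, 0.9398 and 0.5672). Without ct 54, the time of that library, Myl4 in tamoxifen females was at 0.26 and Car3 at 0.22. Sbk3 in tamoxifen males (1.63 ± 0.49, adjusted p = 0.04023) was at 0.79 without the 5 libraries low in Arntl.

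Most metabolic and contractile lists held fewer rhythmic members after tamoxifen, as did all tested genes together (34.53 to 17.12% in females and 55.23 to 8.03% in males). The counts of vehicle males rest in part on the 10 libraries high in TEC counts. Nuclear genes of oxidative phosphorylation were rhythmic for 17 and 13 of 26 in vehicle females and males and for none in tamoxifen hearts of either sex. Ion channels went from 13 and 21 of 34 to 6 and 1, sarcomere genes from 8 and 12 of 20 to 1 and 1, glucose and insulin genes from 11 and 15 of 29 to 5 and 2, fatty acid oxidation from 8 and 15 of 32 to 4 and 3, and calcium handling from 4 and 12 of 17 to 4 and 1. The extracellular matrix had 11 and 8 of 24 in vehicle and 9 and 11 in tamoxifen hearts, glucocorticoid targets 12 and 11 of 14 and then 8 and 9, and heat shock genes 13 and 8 of 14 and then 10 and 5. Interferon genes were rhythmic for 10 of 15 in vehicle males and for 2, 1 and 0 in vehicle females, tamoxifen females and tamoxifen males. These are counts of calls and do not test a difference between groups.

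Rhythmic genes numbered 5396 in vehicle females, 8632 in vehicle males, 2675 in tamoxifen females and 1255 in tamoxifen males. With the 10 vehicle male libraries left out the counts were 6856, 2872, 3855 and 2084, so vehicle males no longer had the most. Fitted on each group alone with all 24 libraries the counts were 6658, 5247, 3996 and 1439, so the order of vehicle females and males also depended on the fit. With the collection times of vehicle males exchanged at random, 1 such fit still called 5018 genes. Without the 13 libraries high in Myl7 tamoxifen males had 789, and without ct 34 they had 811. Vehicle females and males shared 3409 rhythmic genes (2980 expected if independent), vehicle and tamoxifen females 1771 (923.6), vehicle and tamoxifen males 837 (693.1), and tamoxifen females and males 864 (214.8).

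The test of each rhythm against the other treatment picked out clock genes in females. Nr1d1, which encodes the nuclear receptor REV-ERB alpha, had the lowest p-value (difference vector 1.30 ± 0.14, adjusted p = 2.97e-09), with a peak at ct 6.68 in vehicle and 9.55 h in tamoxifen females. Arntl, Cry1 (0.60 ± 0.10), Nfil3 (0.76 ± 0.15) and Npas2 (0.84 ± 0.18) changed too. Slc41a3 (amplitude 1.22 to 0.21, adjusted p = 0.0004129), Irf2bp2 (0.55 to 0.11) and the insulin receptor substrate gene Irs2 (0.72 to 0.33) were also among the lowest p-values. In females 37 genes were called, 36 of them rhythmic in vehicle females, and 2414 had an unadjusted p under the threshold. That count moved widely: 15 without ct 50, 57 without ct 18, 228 without the 10 vehicle males, 706 without the 13 libraries high in Myl7, 149 with DESeq2 and 1042 with limma. Adjusted over the list alone, 10 of 26 oxidative phosphorylation genes changed rhythm in females, against none over all genes.

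In males the lowest p-values belonged to Rad21, a cohesin subunit gene (0.29 ± 0.04, adjusted p = 3.958e-05), Ifit1bl1 (0.89 ± 0.13), Larp4b (0.34), Entr1 (0.34), Dhx40 (0.30) and Surf2 (0.33). Of 29 clock members 6 were called. They were Arntl, Npas2 (0.86 ± 0.19), Per2 (1.03 ± 0.23), Nampt (0.51 ± 0.13), Clock (0.33 ± 0.09) and Hlf (0.40 ± 0.12). In all 3237 genes (20.71%) were called, 2986 of them rhythmic in vehicle males. Shuffled treatment labels gave up to 6603. Of the 3237, 363 were called again without the 10 vehicle males. The count was 1218 without ct 34, 1786 without the libraries high in Myl7 and 1 in the second 24 h alone.

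Rhythms of vehicle females and males differed for 5838 genes (37.35% of those tested). Without the 10 vehicle males 2623 did (2278 in the first set). The lowest p-values were those of Zadh2 (peaks at ct 8.89 and 21.58 h, adjusted p = 2.658e-06), Pnrc1 (0.59), Thtpa (1.06), the insulin-degrading enzyme gene Ide (0.53), the potassium channel gene Kcnh2 (0.59 ± 0.08, amplitude 0.54 in females and 0.23 in males) and Srp72 (0.24). Calls with all libraries took in 12 of 29 clock genes, led by Nr1d1 (0.75 ± 0.14) and Wee1 (0.68 ± 0.13). Oxidative phosphorylation had 14 of 26 and ion channels 18 of 34. In tamoxifen hearts edgeR called 6 genes: the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty, whose female counts came almost entirely from the library labelled Tam_F_ct54_559, and Hdgfl3 (0.29 ± 0.06) and the gene model Gm12966, each at adjusted p = 0.0389. Ift80, Ets2, P4ha2, Smc5 and Spred2 were next, with adjusted p from 0.1444 to 0.1723. The count was 0 without Tam_F_ct54_559, without ct 54 and without the libraries high in Myl7, 19 without ct 26, 53 with limma and 11 with DESeq2, and 909 genes had an unadjusted p under the threshold.

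The interaction of sex and tamoxifen on rhythms was led by Rad21 (0.33), Nr1d1 (1.12), Thtpa (1.11), Pygo2 (0.41), Cyb5d1 (0.74) and Mlh3 (0.75), and among clock genes also took in Wee1, Hlf and Dbp. In vehicle males Rad21, Thtpa, Cyb5d1 and Mlh3 peaked close together, at ct 22.09, 22.95, 22.32 and 23.22 h, while Nr1d1 (8.17) and Pygo2 (11.93) did not. The interaction counted 1616 genes, but 19 without the 10 vehicle male libraries (16 of them in the first set) and 1 with the TEC share as a covariate. Whether the named genes are among the 16 is not given here. Single times moved the count as far, with 1 gene without ct 34, 3 without ct 22, 16 without ct 30, 539 without ct 18, 972 without ct 38, 999 without ct 50, 820 without ct 62 and 3396 without ct 26.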

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

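Tests of other splits and orders were chosen before their results were seen, and the fits that leave out each time were fixed before the data were examined. The tests on chosen libraries, the fits without them and the thinning were chosen after the data had been seen. The results listed here drew attention because the effect of tamoxifen differed between females and males, or the rhythm differed between groups, by a test of the difference itself.

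The interaction of sex and tamoxifen on mean levels covered 8181 genes, a count that 1 of 60 splits reached, the real one. The other 59, which exchanged sex labels within each treatment and time point, gave at most 2379. Such splits remove every sex difference, so they argue against a chance assignment of sex but do not test the interaction alone. Both interactions, on means and on rhythms, take in the vehicle sex difference, where sex and run of title numbers could not be told apart. The female-minus-male difference rose with tamoxifen for Inmt (1.71), Cilp (1.48), Ptn (1.33), Thbs4 (1.21), Ccn5 (1.20) and Comp (1.13). It fell for Myl7 (−5.22), Nt5c1a (−2.04), Pm20d2 (−1.59), mt-Nd4l (−1.33), Pdpr (−1.26), Adcy9 (−1.26), Srp54a (−1.21) and Ppara (−1.16). Myl7 lost its call without the 13 libraries high in it (−0.21), and mt-Nd4l (−0.64) and Comp (0.68) lost theirs without the 10 vehicle males. In the second 24 h alone Inmt, Cilp, Ptn, Comp, Myl7 and mt-Nd4l were not called. Rhythms differed by sex for 5838 genes in vehicle hearts (highest other split 3263). Tamoxifen changed 37 rhythms in females (highest other 6). Of 60 splits 1 reached each, but splits within times do not test chance rhythms. In tamoxifen hearts rhythms differed by sex for 6 genes (highest other 2, with 909 genes at an unadjusted p under the threshold). Of these, 4 are Y-linked genes whose female counts come almost entirely from the library labelled Tam_F_ct54_559, and 0 genes were called without it, so that count rests on a single library. The 3237 rhythm changes in males were reached by 4 of 60 splits (up to 6603), so chance cannot be excluded. The interaction on rhythms covered 1616 genes (highest other 9, 1 of 60 splits), with vectors of 0.328 for Rad21, 1.12 for Nr1d1, 1.11 for Thtpa, 0.408 for Pygo2, 0.739 for Cyb5d1 and 0.748 for Mlh3. Yet that count fell to a small part of its size without the 10 vehicle male libraries, and single times moved it from 1 gene without ct 34 to 3396 without ct 26.

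Other comparisons were tested in the same way. Real mean changes numbered 10678 for sex in vehicle hearts (highest other split 7506) and 1201 for sex in tamoxifen hearts (19). Tamoxifen gave 4299 in females (350) and 10936 in males (3929). Of 60 splits 1 reached each, so chance is less likely but not excluded. Other orders of the collection times within a group, fitted on that group alone, gave at most 4 rhythmic genes against 6658 in vehicle females, 59 against 3996 in tamoxifen females and 11 against 1439 in tamoxifen males. The real order gave the most genes in each group (1 of 60 orders). In vehicle males, however, another order gave 5018 against 5247, so a count of that size can arise without the real times. These fits do not test the 8632 rhythmic genes that the shared fit called in vehicle males.

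Vehicle males stood apart in the number of genes that differed from vehicle females, 10678. Neither the 10 libraries with a high TEC share nor depth accounts for the whole of it, since 7323 genes were called without those libraries and 10070 after thinning all libraries to the smallest total. A separate batch stays open and cannot be told apart from sex, because the run of title numbers of the vehicle males holds 0 libraries of other groups, and a sex difference in vehicle hearts stays open as well. The highest count of rhythmic genes may come from the 10 libraries, since with 14 libraries left vehicle males had 2843 rhythmic genes against 3132 in vehicle females with 14 libraries at the same times, but it also depends on the shared fit, since each group fitted alone with all 24 libraries gave 5247 in vehicle males against 6658 in vehicle females. The TEC share of vehicle males did not follow the time of day past the threshold (R2 19.6%, permutation p = 0.102, adjusted p = 0.407 over 4 groups).

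Arntl lay under 6 CPM in 5 tamoxifen libraries. A score over 288 genes that respond to tamoxifen, chosen without these 5 and set to 0 for vehicle and 1 for tamoxifen hearts, was 0.0807 for Tam_F_ct58_565, and 0.434, 0.415, 0.162 and 0.73 for Tam_M_ct34_526, Tam_M_ct38_531, Tam_M_ct54_556 and Tam_M_ct58_562. A swap with vehicle libraries is argued against, since the highest vehicle score was 0.286 and no vehicle library reached the tamoxifen range (lowest other tamoxifen libraries 0.807 in females and 0.811 in males). Of the 5, 3 lay above the highest vehicle library of their sex (0.144 in females, 0.286 in males), which argues against a vehicle heart under each of the 5 labels, while Tam_F_ct58_565 and Tam_M_ct54_556 lay within the vehicle range, where the first may be one and the second differed from vehicle males of its time in Arntl, Per2 and Ciart. A partial response to tamoxifen is a candidate explanation, as 5 of 5 lay below every other tamoxifen library of their sex, and it was found and tested on the same data.

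The library labelled Tam_F_ct54_559 held Xist at 0.0965% of the median of the other tamoxifen females, which argues against male RNA mixed into a heart with an inactive X. A swap with a male library is argued against too, since 4 of 4 Y-linked genes lay below the lowest male library, at 7.28% of the male median for Ddx3y, 8.6% for Eif2s3y, 10.2% for Kdm5d and 7.59% for Uty. Its 6 escape genes other than Xist had a median position of 0.752 between the female (0) and male (1) medians, where other tamoxifen females ran from −0.173 to 0.227 and the lowest male was at 0.721. Over 1026 autosomal genes with a sex difference it sat at −0.317, within the female range of −0.411 to 0.507 and below the males (0.262 to 1.36). A female heart with a single X chromosome and a small share of Y-bearing cells or male RNA is a hypothesis that these values could fit, and no independent test of it was possible here.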

How the results depend on the processing

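The alternatives that leave out libraries by a measured value, use the TEC share as a covariate, thin the counts or correct for length and GC content were chosen only after the results were seen, and the others were planned. Over the alternatives for single genes, 30435 values kept their direction and their side of the threshold, 1194 lost a call, 38 reversed and the others gained a call. The DESeq2 size factors and thinning moved no count of genes by more than 1.5 times, so the lower depth of the vehicle males did not set these counts. Of simulated rhythms with an amplitude of 0.2, 46% were recovered in vehicle females, in counts with far fewer changed genes than were called here. No paired analysis was possible because no title number occurs in more than 1 group, so the numbers pair no libraries. The 12-level time factor was fitted for means only, the 12 h harmonic for rhythms only, the title number term for tamoxifen libraries only, and the gene lists only with the settings given for them. DESeq2 gave some named genes no adjusted p, and these have no value there.

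Counts that moved by more than 1.5 times follow by alternative, and the cause was not tested except where a fold limit, fewer libraries or fewer times make the test stricter by construction. Limma gave 2797 changed genes by sex in tamoxifen hearts and 6992 for tamoxifen in females. Rhythmic were 5515 genes in tamoxifen females and 2459 in tamoxifen males. Rhythms differed for 53 genes by sex in tamoxifen hearts, 1042 for tamoxifen in females, 5865 for tamoxifen in males and 5494 for the interaction. DESeq2 gave 11 rhythm differences for sex in tamoxifen hearts and 149 for tamoxifen in females. Library size alone gave 62 rhythm differences for tamoxifen in females. No filter gave 501 genes in the interaction of rhythms. A fold of at least 1.5 gave 1378 changed genes by sex in vehicle hearts, 214 for sex in tamoxifen hearts, 477 for tamoxifen in females, 1563 for tamoxifen in males and 1272 for the interaction. Rhythmic were 1897 genes in vehicle females, 3834 in vehicle males, 1063 in tamoxifen females and 513 in tamoxifen males. Rhythms differed for 3566 genes by sex in vehicle hearts and 1929 for tamoxifen in males. A fit on only the groups compared gave 1887 changed genes by sex in tamoxifen hearts. Rhythmic were 5247 genes in vehicle males. Rhythms differed for 410 genes by tamoxifen in females and 991 for tamoxifen in males. The first 24 h alone gave 5.6e+02 changed genes by sex in tamoxifen hearts (295 higher and 263 lower) and 2264 for tamoxifen in females. Rhythmic were 1232 genes in vehicle females, 1166 in tamoxifen females and 488 in tamoxifen males. Rhythms differed for 0 genes by sex in tamoxifen hearts and 3 for tamoxifen in females. The second 24 h alone gave 392 changed genes by sex in tamoxifen hearts, 2215 for tamoxifen in females and 4966 for the interaction. Rhythmic were 3895 genes in vehicle males, 740 in tamoxifen females and 230 in tamoxifen males. Rhythms differed for 1203 genes by sex in vehicle hearts, 3 for tamoxifen in females, 1 for tamoxifen in males and 0 for the interaction. A linear trend gave 469 genes in the interaction of rhythms. A 12 h harmonic gave 3 rhythm differences for sex in tamoxifen hearts and 81 for tamoxifen in females. A term for title number runs, fitted on the tamoxifen libraries alone, gave 2408 changed genes by sex in tamoxifen hearts, against 1887 in those libraries without the term. Rhythmic were 4026 genes in tamoxifen females and 2126 in tamoxifen males, where each group fitted alone without the term gave 3996 and 1439. Part of these moves thus comes with the choice of libraries and not with the term. Leaving out the 10 vehicle males gave 1899 changed genes by sex in tamoxifen hearts, 6661 for tamoxifen in males and 4463 for the interaction. Rhythmic were 2872 genes in vehicle males and 2084 in tamoxifen males. Rhythms differed for 2623 genes by sex in vehicle hearts, 228 for tamoxifen in females, 4.2e+02 for tamoxifen in males and 19 for the interaction. The TEC share as a covariate gave 2147 changed genes by sex in tamoxifen hearts. Rhythmic were 2093 genes in tamoxifen males. Rhythms differed for 3300 genes by sex in vehicle hearts, 212 for tamoxifen in females, 1567 for tamoxifen in males and 1 for the interaction. Leaving out the 5 libraries low in Arntl gave 123 rhythm differences for tamoxifen in females. Leaving out the library labelled Tam_F_ct54_559 gave 0 rhythm differences for sex in tamoxifen hearts. Leaving out the 13 libraries high in Myl7 gave 789 rhythmic genes in tamoxifen males. Rhythms differed for 0 genes by sex in tamoxifen hearts, 706 for tamoxifen in females and 1786 for tamoxifen in males. Leaving out the 16 libraries in doubt gave 7071 changed genes by tamoxifen in males and 4897 for the interaction. Rhythmic were 3309 genes in vehicle males. Rhythms differed for 3046 genes by sex in vehicle hearts, 0 for sex in tamoxifen hearts, 368 for tamoxifen in females, 940 for tamoxifen in males and 202 for the interaction. The length and GC correction gave 1045 genes in the interaction of rhythms.

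Leaving out each of the 12 times in turn moved the rhythmic genes in tamoxifen males from 811 (without ct 34) to 1411 (without ct 54). Rhythm differences ran from 0 (without ct 54) to 19 (without ct 26) for sex in tamoxifen hearts, from 15 (without ct 50) to 57 (without ct 18) for tamoxifen in females, from 1218 (without ct 34) to 4345 (without ct 42) for tamoxifen in males and from 1 (without ct 34) to 3396 (without ct 26) for the interaction. The fitted amplitudes in tamoxifen females ran from 0.2587 (without ct 54) to 3.894 (without ct 42) for Myl4, from 0.2229 (without ct 54) to 3.785 (without ct 22) for Car3 and from 0.5991 (without ct 54) to 1.978 (without ct 22) for Sbk3. Without ct 54 their fitted phase was reversed, but none of these rhythms was called there.

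The share of vehicle sex-biased genes called with the same sign in tamoxifen hearts was 13.59% without the 10 vehicle males, 13.44% with the TEC share as a covariate, 10.42% without the 16 libraries, 8.031% with the length and GC correction, 5.228% without the 5 libraries and 5.134% after thinning. Gene lists called with an estimated correlation numbered 2, 3, 0, 0 and 0 for sex in vehicle hearts, sex in tamoxifen hearts, tamoxifen in females, tamoxifen in males and the interaction. Fry called 20 for sex in vehicle hearts, 11 for tamoxifen in females, 19 for tamoxifen in males and 13 for the interaction. Without the 10 vehicle males camera called 2 for tamoxifen in males and 3 for the interaction.

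Single genes that reversed were mostly those that follow a few libraries, and the cause was not tested. A rhythm counts as reversed when its fitted peak moved nearer to the opposite time of day, called or not. None of the reversed rhythms given here was still called. In the first 24 h Hspa1b was at 0.1822 for sex in tamoxifen hearts, and reversed amplitudes in tamoxifen females were 0.475 for Myl4, 1.218 for Cfd, 1.387 for Car3 and 0.1595 for Sbk3. In the second 24 h Ppbp was at 0.000118 for tamoxifen in males, and Myl4 at 0.1778 and Dkk3 at 0.3827 in vehicle males. Without the libraries high in Myl7 these amplitudes were 0.3911 for Myl4 and 0.1682 for Dkk3 in vehicle males, and 0.4538 for Cfd, 0.3072 for Car3 and 0.6286 for Sbk3 in tamoxifen females. Without the library labelled Tam_F_ct54_559 Cfd was at 0.4553, Car3 at 0.302 and Sbk3 at 0.6366. Limma put Car3 at 0.2356, and without the 5 libraries low in Arntl Sbk3 was at 0.7891 in tamoxifen males. Without the 16 libraries Cfd was at 0.8694, Car3 at 0.9346 and Sbk3 at 0.6349 in tamoxifen females, Sbk3 at 0.7971 in tamoxifen males, and mean changes were 0.01545 for Tnnt3 and 0.03457 for Wt1 (sex in vehicle hearts) and −0.05581 for Mbp (interaction). Without the 10 vehicle males Tnnt3 was at 0.01498, Wt1 at 0.03285 and Mbp at −0.02731 in the same comparisons. The TEC covariate put Por at −0.001304 for sex in vehicle hearts and Mbp at 0.02562 for tamoxifen in males. The length and GC correction put Rora at −0.09582 and Cryab at 0.008571 for sex in vehicle hearts, mt-Nd4 at 0.01229 for tamoxifen in males, and mt-Nd1 at −0.002678 and Cryab at −0.001226 for the interaction.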

Other observations

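Immediate early genes and members of stress pathways moved in both directions. With tamoxifen in females 3 of 16 immediate early genes rose and 1 fell (edgeR's quasi-likelihood test, Benjamini-Hochberg adjustment), with Ccn1 at 0.42 ± 0.08 (adjusted p = 5.324e-06) and Ier3 at −0.69 ± 0.11 (adjusted p = 2.863e-07). In males 3 rose and 5 fell, with Ier2 at −0.52 ± 0.09 and Ier3 at −0.37 ± 0.11, and the call of Ier2 was lost without the 10 vehicle males high in TEC counts (−0.24, adjusted p = 0.06484). No member differed in mean level between the sexes in tamoxifen hearts. Ddit3, a gene of the integrated stress response, fell in both sexes, from 24.11 to 18.53 CPM in females (−0.36 ± 0.09, adjusted p = 0.001192) and from 36.43 to 20.47 CPM in males (−0.78 ± 0.09, adjusted p = 2.073e-12). In males 6 members of that list rose and 8 fell of 15, and 7 targets of p53 rose and 5 fell of 13. No set test with camera called any of these 3 lists for tamoxifen in either sex.

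Rhythmic immediate early genes numbered 8 and 13 of 16 in vehicle females and males and 6 and 4 in tamoxifen females and males, and their rhythms differed between vehicle females and males for 12 and in tamoxifen hearts for none. Targets of p53 had 3 and 9 of 13 rhythmic members in vehicle females and males and 1 in each tamoxifen group. Tnnt3, a troponin gene on the skeletal muscle list, was expressed at a low level and moved in opposite directions with tamoxifen, from 0.8183 to 1.202 CPM in females (0.55 ± 0.14, adjusted p = 0.001278) and from 1.033 to 0.6789 CPM in males (−0.59 ± 0.15, adjusted p = 0.0003938), with an interaction of 1.14 ± 0.20 (adjusted p = 5.139e-06). Without the 10 vehicle males the male change was at −0.25 and not called (adjusted p = 0.2771), and the interaction was at 0.80 (adjusted p = 0.00526).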
